A study of Mus musculus with 2 samples.

How the data were processed

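Messenger RNA levels were measured in 2 cultures of unsorted mouse bone marrow cells, 1 from wildtype mice and 1 from Cpdm mice. Cpdm names the chronic proliferative dermatitis mutant, a spontaneous mouse line that lacks functional SHARPIN, a subunit of the linear ubiquitin chain assembly complex. Per the labels, both cultures were kept for 10 days in medium with 50 µg/ml ascorbic acid and 10 mM β-glycerophosphate, the usual supplements that drive marrow stromal cells towards mineralising osteoblasts. Per the labels' protocols, 5 µg of total RNA per culture was turned into biotin-labelled cRNA with the Affymetrix in vitro transcription protocol, a method that primes at the poly-A tail. The number of mice behind each culture is not given in the sources used here.

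The authors deposited 1 table of linear MAS5 signal intensity values with 45101 probe sets and 1 column per array. GCOS 1.4 and MAS5 are named in the submitters' processing notes. MAS5 summarises each probe set from its perfect match and mismatch probes and scales each array by 1 factor. The mean signal after leaving out the lowest and highest 2% of probe sets was 100 in both columns, which is what global scaling to that target gives; the target itself is not given in the sources used here. The table holds no detection calls and no error per value. Background settings and the software that exported the values are not given in the sources used here. MAS5 signals below the bulk of the array are noisy. The highest deposited signal was 5156, and array signals can be compressed at the top of the scale, which was not tested here.

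Of the 45037 probe sets that are not controls, 34945 carried exactly 1 gene in the platform annotation used here, 932 carried several genes and 9160 were not listed and stay unnamed. Gene symbols were checked through the Entrez identifier, which matched a current mouse gene record for 34741 probe sets, and none of those symbols changed. No genome build is named with the table, so no coordinates are given. Probe sets whose identifier ends in _s_at or _x_at can bind transcripts of related genes, so the genes they represent are less certain.

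All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. The deposited signals were used without further scaling. A floor was set in each array at the 40th percentile of its non-control probe sets, which is a signal of 18.5 in the Cpdm array and 18.7 in the wildtype array, and lower signals were set to the floor. A gene was called measured if its probe set lay at or above the floor in at least 1 array. Where 1 array lay at the floor, the fold is a lower bound for that probe set and is written as "at least". Each gene was represented by its probe set with the highest mean log2 signal. The comparison is the log2 ratio of the Cpdm signal over the wildtype signal, and genes were counted by a fixed rule of size, a difference of at least 2-fold.

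With 1 array per genotype there is no replicate error, no test between genotypes and no p-value. Measurement error can only be judged within the array pair. The first yardstick is 18 hybridisation spike-in probe sets, bacterial and phage transcripts added in equal amounts to every sample. The second is the disagreement between different probe sets of the same gene. Both cover the array and leave out differences between mice, cultures and RNA preparations. The number of arrays limits the precision.

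Before the data were examined, 32 gene lists, the floor, the fold rule, the alternatives and the rule for naming genes were fixed. For each list with at least 5 measured members, the median log2 ratio was set against the medians of 10000 random lists of other measured genes of the same size, matched on mean log2 signal in 20 bins. The percentile among these describes the 2 arrays and is not a test between genotypes. The 95% intervals of list medians come from 10000 bootstrap draws of the members and describe the spread among members. The naming rule took Sharpin and its partners, the 12 genes with the largest difference in each direction among genes above the floor in both arrays whose probe sets go the same way, the 6 largest bounds in each direction, 4 members of each of the 4 main lists and 2 members of every other list, by size of the difference; predicted and unnamed transcripts were skipped among the largest genes and bounds. Among 100 genes named by that rule, 24 had several probe sets above the floor in both arrays, and 2 of them, Tfrc and Adamts9, had probe sets of opposite sign. Flt1, Fhl1 and Vcan had a further probe set of opposite sign when those above the floor in 1 array were counted too. Among the other genes named, so did Kdm5d, Sfrp1, Nkd2, Adamts4, Slc1a4 and Cxcl1. Of 24 genes named by the rule that passed 2-fold and had another probe set above the floor in both arrays, 14 had one with a fold over 1.5 times smaller or of opposite sign, and 7 had one under 2-fold or of opposite sign. Other genes named in the text were chosen from the gene lists after their values were seen. Listed genes without a probe set that carries exactly 1 gene were not analysed here.

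The procedure was tested on simulated data, in which 200 genes of a simulated array pair with 13601 measured genes were changed by known amounts and each array received noise with an SD of 0.25 log2 units. The changed genes were drawn from those with a mean signal more than 3 log2 units above the floor. Of 100 genes changed by 1.5 log2 units, 87 passed the 2-fold rule, and so did all 100 genes changed by 2.5 log2 units. Among the 13401 unchanged genes, 48 passed. Random unchanged lists of 20 genes fell outside the middle 95% of random medians in 4.5% of 200 draws. The noise was independent and of the same size for every probe set. These rates do not carry over to weak signals or to lists of genes that vary together. The simulation held no differences between mice, cultures or RNA preparations. The 48 unchanged genes that passed therefore give no rate of false calls between 2 cultures. The alternatives tried were centring on the median, quantile normalisation, a lowess correction of the trend with signal, floors at the 25th and 60th percentile or none, the mean over probe sets of a gene, a pseudocount equal to the floor, fold thresholds of 1.5 and 3, agreement of all probe sets, and other ways of drawing random lists.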

Results

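Gene expression was profiled on Affymetrix arrays in unsorted bone marrow cells after 10 days of osteogenic culture, with 1 array for wildtype mice and 1 array for Cpdm mice, which lack functional SHARPIN. The design asks how cultured marrow cells differ without this protein, with the study's title naming differentiation and cytokine production of the mesenchymal cells. No culture was replicated, so every difference below describes these 2 arrays and no p-value is given. The median signal was 27.6 in the Cpdm array and 28.1 in the wildtype array. Of 18193 genes with a probe set, 14055 were measured in at least 1 array and 12395 in both.

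The technical controls of the array pair set the scale for the differences that follow. The 18 hybridisation spike-in probe sets had a mean log2 ratio of 0.01 ± 0.11 (SD, n = 18 probe sets), with single values between -0.22 and 0.20. The disagreement between 2 probe sets of the same gene implied a robust SD of 0.32 log2 units per probe set over 5250 genes. Among 514 genes that differed by at least 2-fold and had a second probe set above the floor, the second probe set went the same way for 460 (89.5%) and also passed 2-fold for 255 (49.6%). The signal of the actin control near the 3′ end over that near the 5′ end was 1.92 in the Cpdm array and 1.61 in the wildtype array, and for GAPDH it was 0.836 and 0.721. The 3 control probe sets for 18S ribosomal RNA were lower in the Cpdm array, with log2 ratios of -2.59, -3.75 and -2.37. This difference lies far outside the range of the spike-ins and runs alongside genotype.

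Sex-linked transcripts also differed between the arrays. Xist, the X-inactivation RNA of female cells, was 4.51-fold higher in the Cpdm culture, with a signal of 1113 against 247. That probe set is of the kind that can bind related transcripts, and the other 2 Xist probe sets were above the floor in Cpdm only, at 100.4 against 12.9 and 55.1 against 11.8. The Y-linked genes Uty, Eif2s3y and Kdm5d were lower there, with log2 ratios of -1.92, -1.63 and -1.62. A second Uty probe set had a log2 ratio of -1.29, and a second Kdm5d probe set, near the floor, read 22.9 against 15.5 in the opposite direction. Y-linked transcripts were thus above the floor in both cultures, while Xist was above it in wildtype by 1 of 3 probe sets. This difference runs alongside every gene group described below.

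Sharpin itself was detected in both cultures at similar levels. The probe set with the higher signal read 162 in the Cpdm array and 197 in the wildtype array, which is 82.2% of wildtype, and the other probe set read 107 and 120, which is 89.4%. Both differences are within the disagreement between probe sets of a gene. The Cpdm mutation is a frameshift that need not remove the transcript, so these signals do not check the genotype labels. The transcripts of the other 2 subunits of the linear ubiquitin complex were measured as well. Rnf31, the catalytic subunit, had a log2 ratio of 0.20, and Rbck1 a log2 ratio of 0.82.

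Across all genes, 821 were at least 2-fold higher in the Cpdm culture and 840 were at least 2-fold lower, together with 12394 that lay between. The largest differences were on the lower side. At least 8-fold lower were 88 genes, and at least 8-fold higher were 15. The median log2 ratio of all measured genes was 0.03, and the log2 signals of genes measured in both arrays correlated with a Pearson r of 0.914 across genes, which are not independent replicates. The counts of higher and lower genes stayed within 1.5 times under every other scaling, and grew to 1741 higher and 1885 lower when no floor was used.

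**Figure D1:**
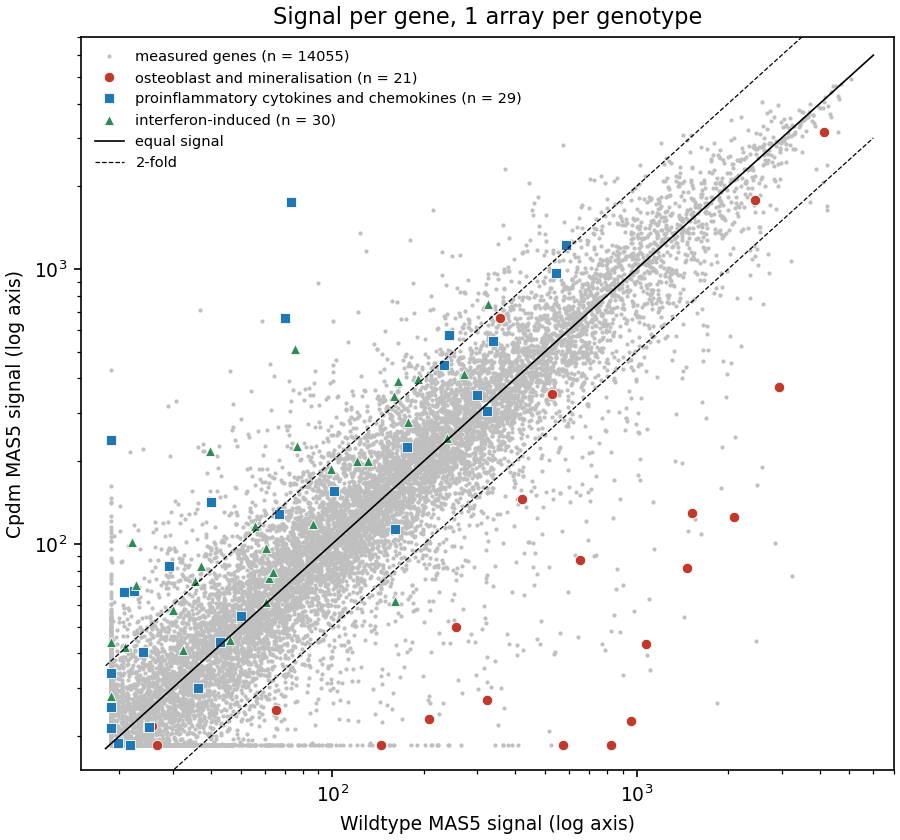
Each point is 1 measured gene, with its wildtype MAS5 signal on the x axis and its Cpdm signal on the y axis, both logarithmic, and signals below the floor drawn at the floor. Coloured markers show 3 gene lists; 15 of the 21 osteoblast genes lie below the lower 2-fold line, while 9 of 29 cytokine genes and 14 of 30 interferon-induced genes lie on or above the upper one.

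The genes with the largest deficit in the Cpdm culture included 4 members of the osteoblast list, Phex, Slc36a2, Col22a1 and Kazald1. Ptprz1, a receptor tyrosine phosphatase, was 69.4-fold lower, with a signal of 26.4 against 1832, and 37.7-fold lower by another probe set. Ptgis, the prostacyclin synthase, was 55.6-fold lower, and the carbonic anhydrase gene Car3 was 42.5-fold lower. Panx3, a pannexin channel of osteoblasts and chondrocytes, was 28.2-fold lower with a signal of 101 against 2842. Pcolce2, an enhancer of procollagen processing, was 19.1-fold lower. The remaining genes of this group were the amino acid transporter gene Slc36a2, Entpd3, Mlip, the neuropeptide gene Gal, the ion channel genes Kcnk1 and Ano1, and Kazald1, which were between 24.6-fold and 42.4-fold lower. The Cpdm signals of Ano1 and Slc36a2, at 20.9 and 22.6, and of Ptprz1 lay near the floor of 18.5, so the size of these folds is uncertain. Among genes whose representative probe set was at the floor in the Cpdm array, the phosphate-regulating endopeptidase gene Phex was at least 44.7-fold lower, Vit at least 32.0-fold, the collagen genes Col22a1 and Col13a1 at least 31.0-fold and 22.1-fold, the sodium-calcium exchanger gene Slc8a3 at least 28.3-fold and Gprc5c at least 21.0-fold lower. Other probe sets, above the floor in both arrays, gave smaller folds of 3.79 for Col22a1 and 4.57 for Gprc5c in the same direction.

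The genes with the largest excess in the Cpdm culture were led by the monocyte-attracting chemokine gene Ccl8, which was 24.0-fold higher with a signal of 1754 against 73.2. The related chemokine gene Ccl12 was 9.55-fold higher. Crabp2, a retinoic acid binding protein, was 19.2-fold higher, and Aldh1a2, an enzyme that makes retinoic acid, was 9.23-fold higher. Vcan, which encodes the proteoglycan versican, was 9.95-fold higher, the glycosaminoglycan enzyme genes Csgalnact1 and Hs6st2 were 11.0-fold and 10.8-fold higher, and Ltbp2 was 11.0-fold higher. The wildtype signal of Vcan, at 21.7, lay near the floor of 18.7. Fhl1 was 11.0-fold, Serpinb2 9.89-fold, the endothelin receptor gene Ednrb 8.99-fold (3.72-fold and 2.27-fold by its other probe sets) and the secreted Wnt antagonist gene Sfrp4 7.66-fold higher. Among genes whose representative probe set was at the floor in the wildtype array, the hyaluronan synthase gene Has2 was at least 22.9-fold higher. Others were Cxcl5 at least 12.8-fold, the macrophage scavenger receptor gene Marco at least 8.64-fold, Cd4 at least 7.83-fold, the stromal surface protein gene Cd248 at least 7.62-fold and Igfbp3 at least 7.51-fold higher, where another Igfbp3 probe set above the floor in both arrays gave 5.12-fold.

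Genes of osteoblasts and mineralisation were lower as a group in the Cpdm culture. Of 21 measured members, 15 were at least 2-fold lower, none was at least 2-fold higher and 6 lay between. The median log2 ratio was -2.97, or 7.81-fold lower, with a 95% interval over members of -3.58 to -1.40. Phex and Col22a1 were at the floor by their representative probe sets, and Slc36a2 and Kazald1 were 42.4-fold and 24.8-fold lower. The osteoblast transcription factor gene Sp7 had a signal of 87.1 against 650, alkaline phosphatase (Alpl) 130 against 1518, the parathyroid hormone receptor gene Pth1r 81.7 against 1460, and the osteocyte genes Dmp1 and Mepe were 7.91-fold and 8.99-fold lower. Ibsp, which encodes bone sialoprotein, differed less, at 3159 against 4130, near the top of the signal range. No random list reached a median as low, and the list stayed below all of its 10000 random lists under each alternative, with medians between -2.99 and -2.66.

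Collagens and matrix-processing genes were lower in part. Of 31 measured members, 11 were at least 2-fold lower, 3 were at least 2-fold higher and 17 lay between, with a median log2 ratio of -0.55 that was below all random lists. The minor fibrillar collagen genes Col24a1 and Col11a1 had log2 ratios of -3.58 and -3.10. The prolyl hydroxylase gene P4ha2 was 8.05-fold lower and the collagen-binding proteoglycan gene Fmod 5.02-fold lower. Col1a1 read 1070 against 3222, whereas Col1a2 was near equal at 3408 against 3432, both near the top of the signal range. Col3a1, Col12a1 and Loxl1 were the members at least 2-fold higher, by 2.05-fold, 2.27-fold and 2.85-fold, with Col12a1 at 1.39-fold by another probe set.

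Adipocyte genes did not stand apart as a list. Of 20 measured members, 2 were at least 2-fold lower and 18 lay between, with a median log2 ratio of -0.16 at percentile 6.45 of random lists. The stearoyl-CoA desaturase gene Scd1 was 6.03-fold lower and G0s2 was 2.25-fold lower. The adipogenic transcription factors differed in sign, with log2 ratios of -0.80 for Pparg and 0.98 for Cebpa. Chondrocyte genes had a median log2 ratio of -0.32 over 14 measured members, at percentile 2.42. Its 4 members at least 2-fold lower included the cartilage matrix genes Comp and Col11a2, which were 15.4-fold and 13.6-fold lower, together with Col2a1 and Snorc. That list moved inside the middle 95% of random lists under 4 alternatives.

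Both stromal lists outside the osteoblast list had medians above 0, with members going both ways. In the marrow stroma and niche list, 7 of 16 measured members were at least 2-fold higher and 1, Pdgfra, was at least 2-fold lower (1.37-fold by another probe set), with a median log2 ratio of 0.61 (95% interval over members -0.10 to 2.08) at percentile 99.93. Hp and the chemokine gene Cxcl14 were 7.10-fold and 5.81-fold higher, and the niche chemokine gene Cxcl12 read 1526 against 736. The median of this list was 0.20 when genes that stand in more than 1 list were left out. In the smooth muscle and myofibroblast list, 6 of 12 measured members were at least 2-fold higher and 1, Des, was lower, with a median of 1.17 (95% interval over members -0.03 to 1.84) above all random lists. The contractile protein genes Tagln and Cnn1 were 4.66-fold and 4.60-fold higher.

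Proinflammatory cytokine and chemokine genes were higher as a group. Of 29 measured members, 9 were at least 2-fold higher, none was at least 2-fold lower and 20 lay between, with a median log2 ratio of 0.70 (95% interval over members 0.20 to 0.95) above all random lists. Ccl8, Cxcl5, Ccl12 and the neutrophil-attracting Cxcl2 led, with Cxcl2 at 3.54-fold. Tnf, the ligand of the receptor that SHARPIN acts downstream of, read 83.2 against 29.0. Cxcl1 was 1.42-fold lower by its representative probe set, but 1.64-fold and at least 5.02-fold higher by its other probe sets. Il1b was near equal at 54.6 against 50.2, and Il6 and Tnfsf11, the gene of the osteoclast factor RANKL, lay below the floor in both arrays. In the list of type 2 cytokines and signals, 2 of 10 measured members were at least 2-fold higher, the receptor gene Il4ra by 3.51-fold (4.36-fold and 1.35-fold by its other probe sets) and Il33 by at least 2.74-fold, and the median was 0.53 at percentile 99.19. That percentile was 58.56 without a floor. The type 2 cytokine genes Il5, Il9, Il13 and Il25 lay below the floor in both arrays. Il4 and Il10 were near it, at 34.8 against 23.2 and 27.7 against 22.8. Of the 10 measured members, 4 lay above the floor in 1 array only. Macrophage genes had a median log2 ratio of 0.46 in the same arrays.

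**Figure D2:**
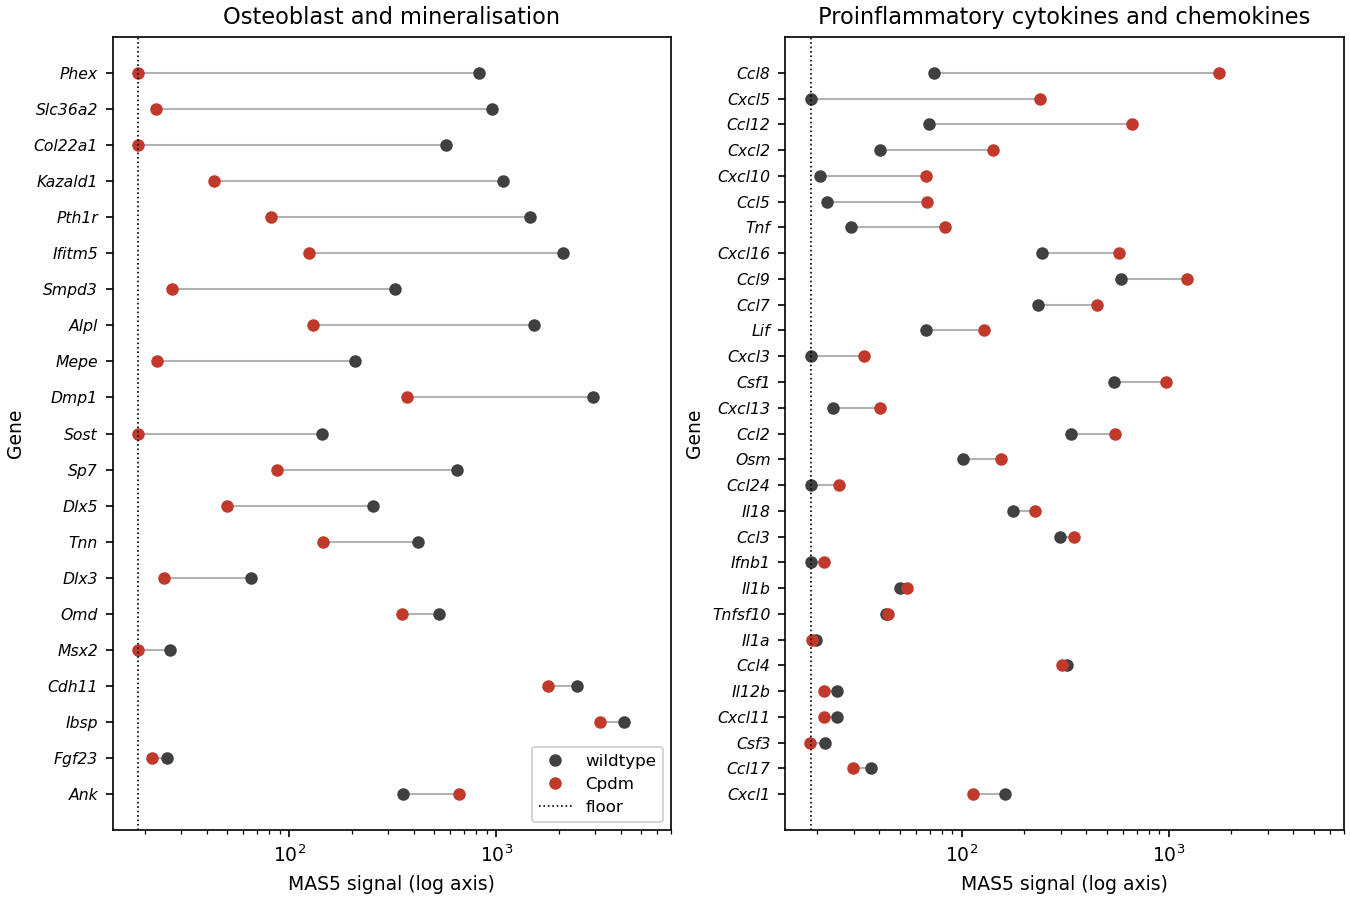
MAS5 signals on a logarithmic x axis of each measured member of the osteoblast list (left) and the cytokine list (right), with wildtype in grey and Cpdm in red and signals below the floor drawn at the dotted floor. All osteoblast genes except Ank have the lower signal in Cpdm, and 22 of the 29 cytokine genes have the higher signal in Cpdm. Each gene is shown by its representative probe set.

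Targets of NF-κB and interferon were higher too. Of 28 measured NF-κB feedback genes and targets, 7 were at least 2-fold higher and 1, the cyclooxygenase gene Ptgs2, was at least 2-fold lower, with a median log2 ratio of 0.54 above all random lists. The adhesion molecule genes Vcam1 and Icam1 were 4.85-fold and 4.55-fold higher, with Vcam1 at 2.26-fold by another probe set. Of 30 measured interferon-induced genes, 14 were at least 2-fold higher and 1, Isg20, was lower, with a median of 0.93 above all random lists. Ifi27l2a and the GTPase gene Gbp2 were 6.75-fold and 5.46-fold higher. Among 24 measured genes of linear ubiquitin assembly and TNF receptor signalling, only Tnfrsf1b passed 2-fold, at 2.06-fold higher by 1 probe set and 1.08-fold by the other, and the necroptosis effector gene Mlkl was 1.79-fold higher. The median of that list was 0.34 (95% interval over members -0.07 to 0.55), at percentile 99.05, and was 0.15 when genes that stand in more than 1 list were left out. In the antigen presentation list 8 of 19 measured members were at least 2-fold higher, with H2-Aa and Cd80 at 5.68-fold and 4.28-fold (1.75-fold and 1.73-fold by other probe sets above the floor in both arrays), and the median was 0.60 at percentile 99.99. Among apoptosis and cell death genes 5 of 20 were at least 2-fold higher, including the death receptor gene Fas at 2.77-fold and the pyroptosis gene Gsdmd at 2.36-fold beside Casp1, Nlrp3 and Zbp1, with a median of 0.40 at percentile 99.34. That percentile was 93.38 with the mean over probe sets.

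Markers of the other cells an unsorted marrow culture can hold were compared in the same way. Macrophage and monocyte genes were high in both arrays, with Cd68 at 3089 and 2545 in the Cpdm and wildtype cultures. Of 27 measured members, 8 were at least 2-fold higher in Cpdm and none lower, with a median log2 ratio of 0.46 above all random lists. Marco was at the floor in wildtype, and the chemokine receptor gene Cx3cr1 was 5.53-fold higher. These genes were thus higher in the same culture as the cytokine, NF-κB, interferon and antigen presentation genes. Osteoclast genes had a median of 0.15 at percentile 77.33. In that list Car2 was at least 9.83-fold lower, and Ctsk, the bone-degrading cathepsin K gene, was 1.95-fold lower. Stromal regulators of osteoclasts had a median of 0.78 over 8 measured members at percentile 99.86, in which the decoy receptor gene Tnfrsf11b was 3.32-fold higher and Ptgs2 3.67-fold lower, Sema3a was the other member at least 2-fold higher, and the percentile was 91.23 with the highest floor.

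The medians of the remaining blood and vessel lists lay within the middle 95% of random lists, while single members differed in both directions. Median log2 ratios were 0.04 for neutrophil genes, -0.10 for mast cell and basophil genes, -0.14 for B cell genes, -0.00 for T and NK cell genes (mean 0.19), 0.02 for megakaryocyte genes and -0.33 for endothelial genes. Of the 11 measured endothelial genes 9 were below 0 (95% interval of the median over members -0.45 to -0.06), and that list reached percentile 1.30 with the highest floor. In these lists the basophil protease gene Mcpt8 was 5.24-fold higher, Kit was 2.39-fold lower and Mcpt2 was also at least 2-fold lower, Cd4 was at least 7.83-fold higher, and Flt1 and Ltf were at least 3.34-fold and 2.06-fold lower. A second Flt1 probe set was near equal, at 20.6 against 19.2. The B cell members Cd22 and Blnk had log2 ratios of 0.99 and 0.90, and Csf3r, Thy1, F2rl2, Gp5 and Esam had values of 0.81, 0.88, 0.93, -0.64 and -0.58. Only 1 eosinophil gene, Prg2, was measured, at 21.9 against 13.3, and 4 erythroid genes, among them the transferrin receptor gene Tfrc. Its probe sets disagreed, at 1.59 and -0.45, and Car1 was at least 1.88-fold lower, since it lay at the floor in Cpdm.

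**Figure D3:**
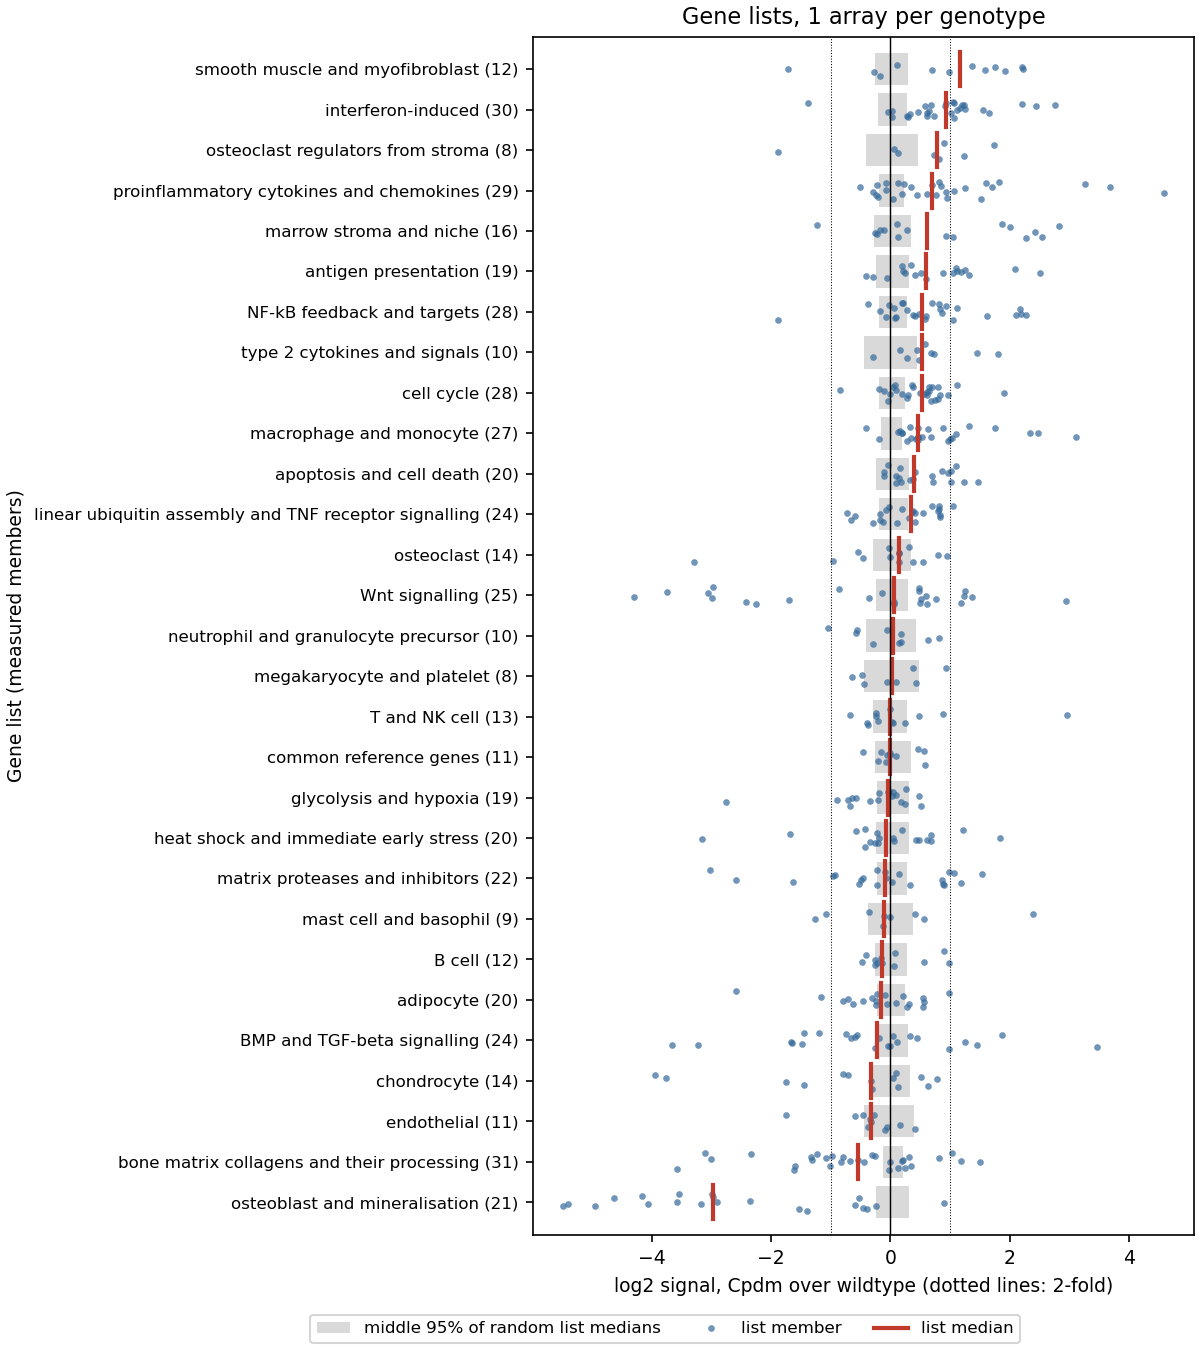
Log2 ratio of the Cpdm signal over the wildtype signal on the x axis for each measured member (points) of 29 gene lists with at least 5 measured members, with the list median in red and the middle 95% of the medians of matched random lists in grey. The osteoblast list has the lowest median, at -2.97, and the smooth muscle list the highest, at 1.17.

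Of the 29 lists with at least 5 measured members, 12 medians lay above the middle 95% of random medians and 4 below it. Random lists would give 1.45 outside, but the genes of a list can vary together and some lists share genes. These counts are not a test. Cell cycle genes had a median of 0.53 above all random lists, with 24 of 28 members above 0, and the proliferation marker gene Mki67 was 3.73-fold and Nusap1 2.16-fold higher. In the Wnt list, 8 of 25 measured members were at least 2-fold lower and 5 were at least 2-fold higher, namely Sfrp4, Sfrp1, Nkd2, Lrp6 and Wnt11. The secreted Wnt inhibitor gene Wif1 was at least 19.7-fold lower and Sfrp2 13.4-fold lower, and the list's median of 0.07 and mean of -0.51 differed in sign. Its median was 0.48 when genes that stand in more than 1 list were left out. In the BMP and TGF-β list, 7 of 24 were at least 2-fold lower, led by the receptor decoy gene Bambi at 12.6-fold, and 4 were higher, Ltbp2, Grem1, Tgfbi and Ccn2. Its median of -0.23 lay at percentile 1.77 and moved inside the middle 95% under 6 alternatives. Matrix proteases and their inhibitors had a median of -0.08, with Mmp16 8.12-fold lower (4.39-fold by another probe set), and with Adamts9 at a log2 ratio of -2.58 by 1 probe set and 0.24 by another. Mmp10, Timp3 and Adamts4 were the members at least 2-fold higher, the last 2 by less than 2-fold or in the other direction by another probe set, and Mmp23 was lower too. Stress genes had a median of -0.07, with Trib3 8.93-fold lower and Hspa1b 3.56-fold higher, and with Ddit3 and Hspb1 past 2-fold in the same directions. Glycolysis and hypoxia genes had a median of -0.04, with Ndrg1 6.74-fold lower and Vegfa 1.86-fold lower. None of the 11 measured common reference genes differed by 2-fold, the largest being Sdha and Hprt at log2 ratios of 0.58 and 0.57, and their median was -0.01.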

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

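Probe sets that could not be tied to a single gene were left out of all comparisons above. Of 4949 such probe sets that were measured, 219 (4.43%) were at least 2-fold higher in the Cpdm culture than in the wildtype control and 178 (3.60%) were at least 2-fold lower, which is why they are listed here. They carry several genes or none in the annotation used here, so no gene is named for them.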

How the results depend on the processing

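All alternatives here were planned, apart from those of the amino acid list, which were chosen after the result was seen. Counts of genes past 2-fold stayed within 1.5 times of the 821 higher and 840 lower genes under median centring, quantile normalisation, the lowess correction, the floors at the 25th and 60th percentile, the mean over probe sets and the pseudocount. Without a floor they were 1741 higher and 1885 lower. With a fold threshold of 1.5 they were 2210 and 1895, and with a threshold of 3 they were 217 and 342. With 2 or more measured probe sets that all passed 2-fold they were 97 and 146, out of 353 and 361 called by the representative probe set among the 6226 genes that have several; a smaller set of genes enters there. No gene named by the rule and at least 2-fold apart changed its direction, and 289 of 291 alternative list medians stayed within the 95% interval of the members. The exceptions were the type 2 list, with a lowest median of 0.04, and the B cell list, whose medians ran from -0.22 to 0.34. The percentile changed its side of the middle 95% in 15 of 290 alternative values, of 6 lists: chondrocyte, type 2 cytokines, osteoclast regulators, endothelial (1.30 with the highest floor), apoptosis, and BMP and TGF-β; the cause was not tested. The osteoblast, bone matrix and cytokine lists kept their side in each alternative, and the adipocyte list stayed between 4.07 and 10.69. Of 797 alternative values of genes named by the rule, 658 lay within the robust SD per probe set. The largest shift of the median of all genes by another scaling was -0.03. No paired analysis was possible because each genotype has 1 array, and no array could be left out. Low signals limit the folds of 5 of the 29 cytokine genes, which lay above the floor in 1 array only.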

Other observations

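The 3 other scalings were planned, whereas the other tests in this part, the limits set for the scalings and both gene lists of this paragraph were chosen after the results had been seen. A list of genes of amino acid synthesis, uptake and tRNA charging, together with stress regulators such as Atf5, Cebpg, Sesn2 and Nupr1, had a median below 0 in the Cpdm culture. It was written only after Chac1, Trib3, Ddit3, Slc7a5, Aldh1l2 and Vldlr had been seen among the lower genes, and its members are known to respond to the transcription factor ATF4. Without those 6 genes, 19 of 30 measured members were at least 2-fold lower and none was at least 2-fold higher, with a median log2 ratio of -1.14 (95% interval over members -1.59 to -0.89) below all of 10000 matched random lists. The serine synthesis genes Phgdh, Psat1 and Psph were 7.16-fold, 4.46-fold and 3.21-fold lower, the asparagine synthetase gene Asns 5.75-fold lower, the glycine transporter gene Slc6a9 4.55-fold lower and the proline synthesis gene Aldh18a1 3.66-fold lower. The smallest folds by other probe sets were 2.61 for Phgdh, 2.49 for Slc6a9 and 1.62 for Aldh18a1. Of the 8 measured aminoacyl-tRNA synthetase genes on that list, Cars, Iars and Sars were 2.87-fold, 2.29-fold and 2.24-fold lower. Gars, Aars, Lars, Wars and Nars stayed under 2-fold, at 1.94-fold, 1.73-fold, 1.70-fold, 1.45-fold and 1.35-fold lower. Synthetase genes outside the list are not described here. Atf4 itself read 819 against 1803. Slc1a4 was the only member above 0, at a log2 ratio of 0.90, and another of its probe sets, at the floor in Cpdm, went the other way. Chaperone and folding genes of the endoplasmic reticulum, listed after the same look, had a median of -0.37 over 16 members, at percentile 0.32, and lay above that list by 0.78 log2 units (95% bootstrap interval over members 0.43 to 1.31).

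The first pattern is the deficit of osteoblast and mineralisation genes in the Cpdm culture. Array scaling is argued against only for the list relative to the other genes, where the highest list median under the 3 other scalings was -2.96. The largest shift of the median of all genes by these scalings was -0.03, and each takes most genes as equal. They cannot test a difference that spans the whole array. For the genes of both stromal lists, a lower share of mesenchymal cells among blood-derived cells is argued against as the only cause. It needs the 28 measured genes of the marrow stroma and smooth muscle lists to be lower by about as much as the osteoblast genes. Their median log2 ratio was 0.96 (95% interval over members 0.11 to 1.82). Alone, the lists had intervals starting at -0.10 and -0.03, and the stroma median was 0.20 without genes that stand in more than 1 list. Vcam1, among these genes, also stands in the NF-κB list. The bone matrix list was left out of this test and went the other way. Of its 31 measured members, 21 were below 0, with a median of -0.55, a smaller deficit than the osteoblast median of -2.97. A smaller share offset by higher expression in each cell was not tested. Fewer osteoblast-lineage cells among the stromal cells, or less expression in each of them, may both underlie the pattern and were not separated here. A different mix of male and female cells, or any other difference between the 2 cultures, cannot be told apart from genotype with 1 sample per genotype.

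The second pattern is the excess of cytokine, NF-κB and interferon-induced genes. Relative to the other genes, array scaling is argued against, since the median of the 3 lists together was at least 0.66 under each of the 3 other scalings. As above, a difference that spans the whole array was not tested. A larger share of macrophages remains a candidate explanation, and 2 of the 27 macrophage genes also stand in another list. Of the 11 macrophage genes with both signals over 2000, 9 were higher in Cpdm and 2 were lower: C1qb read 3959 in Cpdm and 2926 in wildtype and C1qc 3552 and 3188, while Lyz2 was lower in Cpdm at 2657 and 3507, as was Gpnmb at 2449.8 and 2779.7. Outside the macrophage list, the 87 measured genes of the 3 lists had a median of 0.70 against 0.46 for the macrophage list, a difference of 0.24 whose 95% bootstrap interval of -0.28 to 0.46 includes 0. Those 11 genes had a median of 0.34 and the other 16 had a median of 0.99, and it was not tested whether high signals are compressed on these arrays.

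The third pattern is the higher Xist and lower Y-linked signal in the Cpdm culture, in which both lay above the floor. Pools of male and female mice in different shares may explain it as a hypothesis. The 3 Y-linked genes differed from each other by 0.29 log2 units, less than 2 robust SD per probe set (0.64). The 4 Y-linked probe sets above the floor in both arrays spanned 0.63, close to that limit. A second Kdm5d probe set near the floor went the other way, and Xist was above the floor in wildtype by 1 of 3 probe sets, so whether the wildtype culture held female cells stays open. The labels used here give neither the sex nor the number of mice. The 18S ribosomal RNA controls, lower in Cpdm by log2 ratios of -2.59, -3.75 and -2.37, lie outside the spike-in range of -0.22 to 0.20 and are reported as values only. A difference in RNA preparation cannot be told apart from genotype here.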
